A study of Homo sapiens with 12 samples.

How the data were processed

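RNA of CUTLL1 cells was measured on 12 one-colour Agilent arrays, 1 per sample. The labels give 4 groups of 3 replicates: DMSO and GSI (Compound E, 1 µM), each harvested 12 h and 48 h after treatment. Per the labels' protocols, total RNA was purified on columns with DNase treatment and converted to Cy3-labelled cRNA. The array combined 34134 catalogue probes with 23042 custom probes for long noncoding RNAs, on 62976 spots of which 61537 were not controls.

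The authors scanned the arrays and extracted spot intensities with Agilent Feature Extraction 10.5.1.1 and design coordinates on hg19, per the file headers, whereas the submitters' processing notes name version 9.1. The deposited processed signal of each spot is an intensity on a linear scale. Per the file headers' protocol it is background-subtracted and spatially detrended, with surrogate values for dim spots, and it was not normalised between arrays. The authors also deposited a value table of the same arrays on a log2 scale for 36611 probes. Each of its columns correlated best with its own array (r from 0.988 to 0.993 across probes, against at most 0.983 with another array) and rose with that array's log2 signal with a slope of 0.996 to 1.00 over bright probes. Column medians were 6.95 to 7.14. The scale and direction are therefore those of log2 signal, while the centring and normalisation between arrays stay unknown, being not given in the sources used here. It served only as an alternative.

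For the main analysis, control spots and spots marked as outliers were left out, log2 of the processed signal was taken minus the 75th percentile of that array, and the spots of a probe were averaged. A probe was kept if at least 0.5 of its spots were well above background on all 3 arrays of at least 1 group, which left 29801 of 57176 probes. Where a gene had several kept probes (3684 features), the one with the highest mean represented it, and disagreeing probes are given beside the gene. This gave 25384 features. Names came from the accessions in the files: 25742 of 27266 probes with a RefSeq accession matched a RefSeq gene table of assembly GRCh38.p14, used only for names and biotype, and 31434 probes had no symbol and kept the file's identifier. Since the builds differ, no coordinates are given. Class followed the RefSeq biotype, and custom probes without a match were counted as noncoding from the name of the array design. Of the features 14114 had a symbol, 362 were of another class and 3739 stayed unclassified.

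Differences were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3, package data.table in version 1.17.8) over all 4 groups without covariates, with 8 residual and 3.08 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all features, separately for GSI against DMSO at 12 h, the same at 48 h, the difference of those effects, and DMSO 48 h against 12 h. The threshold was 0.05. Errors are standard errors of the fit. Where a gene was not well above background on any array of a group, the difference is a bound: the mean of the brighter group is set against the higher of the lowest well-above-background signal and the probe's own signal on each dim array, as means of normalised log2 values. Such a bound limits the dim side only. It is an estimate from 3 bright arrays, not a confidence limit, and can be lower with 1 array left out. That of TCONS_00003874 at 48 h went from 11.4-fold to 9.63-fold without DMSO replicate 2. Gene lists were tested against all other features with camera at a preset correlation of 0.01, over 25313 features without missing values and adjusted over 24 lists. Camera with an estimated correlation and fry served as alternatives. For the 2 lists chosen later, camera values were adjusted over those 2 lists and 4 comparisons together. The lists were NOTCH targets, ribosome biogenesis, ribosomal proteins, DNA replication, mitosis, cholesterol synthesis, glycolysis, the ATF4 amino acid response, nucleotide synthesis, oxidative phosphorylation, T cell receptor and thymocyte genes, FOXO targets, PI3K signalling, p53 targets, apoptosis regulators, NF-kB targets, interferon response, immediate early and heat shock genes, noncoding growth genes, and markers of B, myeloid, erythroid, natural killer and stromal cells. Some genes stood in more than 1 list, such as BTG2 among FOXO and p53 targets.

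The groups, the tests, these lists, most alternatives and the rule for naming genes were set before the data were examined. The rule named, per GSI comparison, the 10 largest rises and 10 largest falls among called genes with a symbol whose groups did not overlap, the 5 largest rises and falls of noncoding features, up to 4 members of each described list with the smallest p, and every measured NOTCH target. For DMSO over time and for the difference between the times it named the 5 largest changes per direction. Clone and prediction names were skipped among the largest changes. Of unnamed transcripts, only 2 that rose and 2 that fell are given here.

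Whether replicate numbers pair the arrays was checked from the deviations of each array from its group mean. Same-numbered GSI and DMSO arrays of 1 time correlated at 0.352 to 0.543 in all 6 pairs, above the set minimum of 0.1, against -0.371 to -0.0174 for other numbers. Deviations within a group sum to 0, so positive values for same numbers push the others below 0. Only the same-number values therefore bear on pairing. Across times, arrays of the same treatment and number gave -0.0161 to 0.146. The numbers therefore pair GSI with DMSO within a time, which also matches the slides, and values with that pair as a block are given where they change a call. Replicates of a group correlated at 0.984 to 0.991 across probes. The arrays lay on 4 slides scanned on 3 dates: slides 1 and 2 each held a 12 h pair, slide 3 a 48 h pair and slide 4 the remaining 6 arrays.

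Alternatives were quantile normalisation, scaling to the array median, normexp background correction, no filter on dim probes, only probes well above background on all arrays, the mean of all probes of a gene, the deposited table, only the compared arrays, an intensity trend with robust fitting, array weights, blocks for replicate number and slide, and leaving out each array in turn. Normexp was planned on mean spot signals and run on median spot signals, offset 50, because the files hold no mean signal. That run, the pair block within each time, scan date as a block, slide 4 alone and the slide block for gene lists were added after seeing the data.

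The fits were tested on simulated data with 200 of 25384 genes changed. At 12 h, 8% of genes changed 1.5-fold were recovered, 48% at 2-fold, 92% at 4-fold and 96% at 8-fold. The shares were 4%, 56%, 92% and 100% at 48 h, 2%, 22%, 72% and 94% for the difference between times, and 10%, 58%, 92% and 100% for DMSO over time. False calls made up 4.69%, 5.97%, 4.04% and 6.47% of calls in that order, and 0 were made with nothing changed. In 20 draws of the 12 h design with glycolysis shifted by 0.5, camera found it in 20, with 1 other list called, and with nothing shifted called 0. Noise in all simulated data was independent between genes and held no pairs of arrays. The draws therefore cannot tell how often camera calls lists of unchanged genes that correlate, as genes on real arrays do.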

Results

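Expression was measured in CUTLL1 cells, a human T cell acute lymphoblastic leukaemia line that carries a rearranged, active NOTCH1. The cells received Compound E at 1 µM, a gamma-secretase inhibitor (GSI) that blocks the cleavage releasing the active part of NOTCH receptors, or its solvent DMSO. RNA was taken 12 h and 48 h later, which gave 4 groups of 3 arrays and 12 one-colour arrays in all. Each array held 57176 probes, of which 23042 had been added for long noncoding RNAs. The 75th percentile of the processed signal lay between 217 and 415 intensity units, and 28067 to 34183 probes per array were well above background. After filtering, 25384 features were compared, of which 13714 were coding and 7569 noncoding. The number of arrays limits the precision of every value. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

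The first comparison asked which transcripts GSI had changed by 12 h. Direct NOTCH targets gave several of the largest falls (log2 difference GSI minus DMSO ± SE, n = 3 arrays per group). NRARP, which encodes a feedback inhibitor of NOTCH, fell by 3.62 ± 0.20, DTX1, a ubiquitin ligase of the pathway, by 2.79 ± 0.19, and the HES repressor gene HES5 by 2.85 ± 0.36. The kinase gene WNK2, not on the list of NOTCH targets, fell by 2.86 ± 0.22. FBXO2, a ubiquitin ligase subunit that binds glycoproteins, was at least 7.82-fold lower with GSI, where its probe was not well above background on any array (limma adjusted p = 0.00181). The same held for EXD3 (at least 5.13-fold), CLCA1 (3.62-fold, and 1.90-fold without DMSO 12 h replicate 1), ACY3 (3.14-fold), the antisense transcript UMODL1-AS1 (2.95-fold) and CPA4 (2.52-fold). Without DMSO 12 h replicate 2 the bounds of FBXO2 and CPA4 were 6.57-fold and 1.98-fold.

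The largest rises at 12 h were in SCG2, a secretory granule protein gene (2.86 ± 0.58), the acid sphingomyelinase gene SMPD1 (2.08 ± 0.23), the T cell cytokine gene IL2 (2.07 ± 0.34), FRY (2.03 ± 0.28) and the cytokine gene IL26 (2.00 ± 0.27). RLN1 rose by 1.84 ± 0.25, the pseudokinase gene TRIB1 by 1.76 ± 0.35, the ubiquitin ligase gene RNF125 by 1.67 ± 0.21, ARID5B by 1.57 ± 0.19 and the prostaglandin D2 receptor gene PTGDR2 by 1.53 ± 0.24. In DMSO, SCG2 and IL2 were well above background on 2 of 3 arrays and RLN1 on 1 of 3. FRY had several probes, whose differences ran from 1.22 to 2.03.

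Of 20 measured NOTCH targets, 10 fell at 12 h, none rose and 10 did not pass; 15 fell when p was adjusted over the list alone. Besides NRARP, DTX1 and HES5, the fallers were the receptor gene NOTCH3 (-1.91 ± 0.22), CR2 (-1.84 ± 0.34), GIMAP5 (-1.72 ± 0.26), PTCRA, the invariant chain of the pre-T cell receptor (-1.48 ± 0.21), HES4 (-1.40 ± 0.18), SHQ1 (-1.23 ± 0.18) and RUNX3 (-0.84 ± 0.16). MYC, a direct target that drives growth in these leukaemias, differed by -1.06 ± 0.22 (limma adjusted p = 0.0572), and passed with GSI and DMSO arrays paired (0.0114). HEY1 (-3.58 ± 0.77, adjusted p = 0.0639), HES1 (-0.71 ± 0.21, 0.209) and NOTCH1 itself (0.03) did not pass. FJX1 (-1.83, adjusted p = 0.218) and IGF1R (-0.49, 0.252) passed only with the pairing (0.0329 and 0.0490). IL7R (-0.19), TRIB2 (-0.20), CCND3 (0.36) and LFNG (-0.10, with probes from -0.10 to 0.75) did not pass either. The list's median was -1.32 (camera adjusted p = 4.54e-23, and 0.00207 with an estimated correlation, but 0.269 when that was combined with the pairing). Within the 12 h pairs it was -0.99 on slide 1, -1.21 on slide 2 and -1.57 on slide 4.

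**Figure D1:**
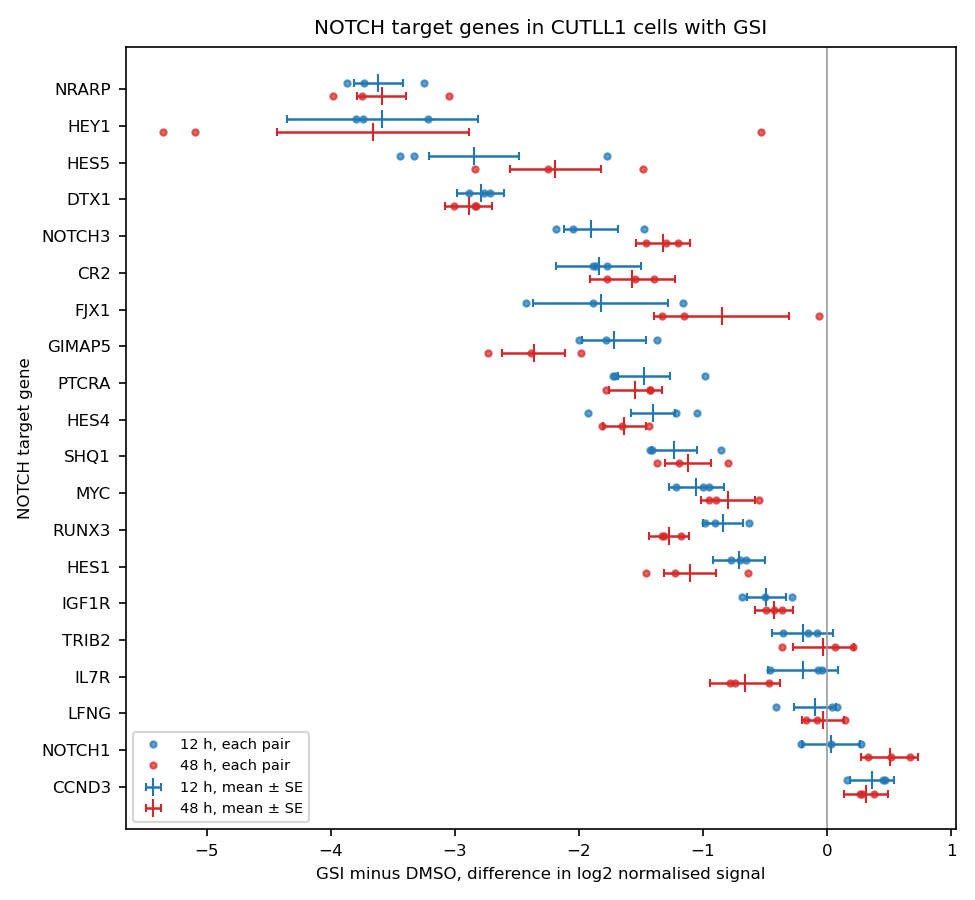
Differences in log2 signal, GSI minus DMSO, for the 20 measured NOTCH targets at 12 h and 48 h, with a tick for the fitted value, a bar for its standard error (3 arrays per group) and a point for each pair of arrays. The fitted value of NRARP lies at -3.62 and -3.59 at the 2 times, while NOTCH1 lies at 0.03 and 0.50.

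Genes of ribosome biogenesis moved down as a group at 12 h: all 35 had negative differences, with a median of -0.57, although 0 passed among all genes by limma and 22 fell when adjusted over the list alone (camera adjusted p = 1.20e-22; adjusted p = 0.273 with an estimated correlation). WDR12 differed by -0.81 ± 0.17 (adjusted p = 0.0501), PUS7 by -1.26 ± 0.27 (0.0595), DKC1 by -0.65 (0.111) and the helicase gene DDX21 by -0.72 (0.111), and all 4 passed with the pairing (0.0220, 0.0165, 0.0336 and 0.0177). Nucleotide synthesis genes shared the direction, with 21 of 25 negative and a median of -0.34, and -0.18 without DMSO 12 h replicate 3 (camera adjusted p = 2.13e-05; adjusted p = 0.441 with an estimated correlation). Among them PPAT, the first enzyme of purine synthesis, differed by -0.56 (adjusted p = 0.201, and 0.0336 with the pairing) and IMPDH2 by -0.63 (0.205, and 0.0441). Of 23 growth-related noncoding genes that host small nucleolar RNAs or accompany growth, 19 were negative, with a median of -0.29 (camera adjusted p = 0.000106; adjusted p = 0.107 with an estimated correlation). CYTOR differed by -0.51 ± 0.11 (adjusted p = 0.0804, and 0.0362 with the pairing) and PVT1, next to MYC, by -0.88 ± 0.30 (0.298).

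FOXO targets, genes active in resting cells, moved up at 12 h: 3 of 24 rose, 1 fell and 20 did not pass (the same counts over the list alone), with a median of 0.21, and 0.32 and 0.11 without DMSO 12 h replicates 1 and 2 (camera adjusted p = 0.00278; adjusted p = 0.273 with an estimated correlation). The homing receptor gene CCR7 rose by 0.99 ± 0.17, the antiproliferative gene BTG2 by 0.95 ± 0.18 and CCNG2 by 0.91 ± 0.18, while GADD45A fell by 0.84 ± 0.16. The call of CCNG2 was lost whichever 12 h array was left out, and those of CCR7, BTG2 and GADD45A in most cases. Mitotic genes were slightly higher, 36 of 37, with a median of 0.18 and 0 called by limma (camera adjusted p = 0.000102; adjusted p = 0.601 with an estimated correlation). That list did not pass without DMSO 12 h replicate 2 (median 0.04, adjusted p = 0.0663). Natural killer and cytotoxic genes were positive in 8 of 10, with a median of 0.63, 0 called, and 4 up and 1 down when adjusted over the list alone (camera adjusted p = 0.00226; adjusted p = 0.113 with an estimated correlation). GZMA, a killer cell protease, differed by 1.83 ± 0.39 (adjusted p = 0.0639, and 0.0154 with the pairing), PRF1 by 0.85 (0.132, and 0.0157) and the receptor gene KLRD1 by -1.38 ± 0.45 (0.264, and 0.0193).

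The other 17 lists did not pass at 12 h. Their medians were -0.05 for ribosomal proteins (camera adjusted p = 0.202), 0.03 for DNA replication (0.470), 0.10 for cholesterol synthesis (0.0682, and 0.0419 with the pairing), -0.07 for glycolysis (0.316), -0.16 for the ATF4 amino acid response (0.316) and -0.05 for oxidative phosphorylation (0.183). T cell receptor and thymocyte genes had a median of -0.03 and a positive mean (0.971), PI3K signalling -0.07 (0.193), p53 targets 0.09 (0.316), apoptosis regulators 0.12 (0.193), NF-kB targets 0.11 (0.0590), interferon response 0.03 (0.193) and immediate early genes 0.02 (0.499). Markers of other cell types had medians of -0.12 for B cells (0.316), -0.13 for myeloid cells with a positive mean (0.855), 0.04 for erythroid cells with the test pointing down (0.855) and 0.12 for stromal cells (0.470). Single members passed in 4 of these lists: the kinase gene ZAP70 fell by 0.74 ± 0.15, and CD83 (0.74 ± 0.15), the p53 target list's member BTG2 and the myeloid gene CEBPE (1.00 ± 0.19; adjusted p = 0.0522 with the pairing) rose. GATA3 (1.01 ± 0.22, adjusted p = 0.0622) and CD69 (0.73, 0.0841) did not pass but did with the pairing (0.0127 and 0.0280).

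In all, limma called 233 of 25384 features at 12 h at an adjusted p under 0.05, 77 higher and 156 lower with GSI, of which 173 changed at least 2-fold. With each GSI array paired with the DMSO array of its number, 1171 were called (570 and 601). When each array was scaled to its median, 172 were called and the share that rose went from 33.0% to 20.9%. The 3 GSI arrays all lay on one side of the 3 DMSO arrays for 15.7% of features, against 10% by chance for arrays that do not pair. The count was 138 without GSI replicate 1, 123 without DMSO replicate 2, 134 without GSI replicate 2, 133 without DMSO replicate 3 and 120 without GSI replicate 3. Of 44 named calls, 9 were lost without DMSO replicate 1, 16 without GSI replicate 1, 17 without DMSO replicate 2, 15 without GSI replicate 2, 20 without DMSO replicate 3 and 19 without GSI replicate 3. SCG2, CCNG2 and CD83 were lost whichever was left out. IL2, TRIB1, CLCA1, ACY3, UMODL1-AS1, CR2, RUNX3, CCR7, BTG2, GADD45A, ZAP70 and CEBPE were lost in most cases, and PTGDR2 and EXD3 in some.

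The second comparison asked the same of cells treated for 48 h. The keratin gene KRT1 rose most (3.83 ± 0.44), followed by EGR2, a transcription factor induced by T cell receptor signals (3.24 ± 0.49), PTGDR2 (2.67 ± 0.24), C2CD4B (2.62 ± 0.35) and TRIB1 (2.35 ± 0.35). MTCL1 (2.30 ± 0.31), AHNAK (2.26 ± 0.46), the laminin gene LAMA3 (2.15 ± 0.27), RASGRP1, an activator of RAS in T cells (1.81 ± 0.30), and SVOPL (1.79 ± 0.32) also rose. In DMSO, EGR2, C2CD4B, AHNAK and LAMA3 were well above background on 1 of 3 arrays, as was SPON1 with GSI. NRARP fell by 3.59 ± 0.20, TMEM158 by 3.59 ± 0.43, SPON1 by 3.25 ± 0.49, WNK2 by 3.19 ± 0.22 and DMBT1 by 3.04 ± 0.56. With GSI the probes of FBXO2, the phosphodiesterase gene PDE4B, GSAP and KLRD1 were not well above background on any array, which put them at least 5.09-fold, 4.92-fold, 4.77-fold and 4.19-fold lower (limma adjusted p = 0.00143, 0.0122, 0.00160 and 0.00110). Without DMSO 48 h replicate 1 the bound of PDE4B was 2.73-fold.

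NOTCH targets were again low: 11 of 20 fell, none rose, 9 did not pass, and 14 fell when adjusted over the list alone. DTX1 fell by 2.89 ± 0.19, GIMAP5 by 2.36 ± 0.26, HES5 by 2.19 ± 0.36, HES4 by 1.63 ± 0.18, PTCRA by 1.54 ± 0.21, NOTCH3 by 1.32 ± 0.22, RUNX3 by 1.27 ± 0.16, SHQ1 by 1.12 ± 0.18 and HES1 by 1.11 ± 0.21. HEY1 fell by 3.66 ± 0.77 but did not pass with the pairing (adjusted p = 0.0795), and its GSI probe was well above background on 1 of 3 arrays. CR2 (-1.57, adjusted p = 0.0572), MYC (-0.80, 0.162) and IL7R (-0.66, 0.510) did not pass but did with the pairing (0.00211, 0.0157 and 0.0341), while NOTCH1 (0.50), IGF1R (-0.43), CCND3 (0.31), LFNG (-0.04), TRIB2 (-0.03) and FJX1 (-0.85) did not pass. The list's median was -1.20 (camera adjusted p = 1.69e-22, and 0.00226 with an estimated correlation, but 0.0999 when that was combined with the pairing), with -1.20 in the pair on slide 3 and -1.32 and -1.27 in the 2 pairs on slide 4.

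T cell receptor and thymocyte genes were higher at 48 h: 3 of 35 rose, 7 rose and 1 fell when adjusted over the list alone, and the median was 0.16 (camera adjusted p = 0.000112; adjusted p = 0.313 with an estimated correlation). RAG1, which cuts DNA for receptor gene rearrangement, rose by 1.63 ± 0.24, the thymic chemokine receptor gene CCR9 by 1.65 ± 0.29 and GATA3 by 1.18 ± 0.22. RAG2 differed by 0.64 (adjusted p = 0.0729, and 0.0125 with the pairing). Among FOXO targets, 2 of 24 rose, BTG2 (1.18 ± 0.18) and CCR7 (0.89 ± 0.17), 4 over the list alone, with a median of 0.27, and 0.16 without DMSO 48 h replicate 2 (camera adjusted p = 0.000147; adjusted p = 0.223 with an estimated correlation). CD83 (0.81 ± 0.15) was the 1 member of 18 NF-kB targets to rise, 2 over the list alone, and their median was 0.16 (camera adjusted p = 0.0144; adjusted p = 0.223 with an estimated correlation). NF-kB targets did not pass without GSI 48 h replicate 1 (0.09, adjusted p = 0.158) or DMSO 48 h replicate 2 (0.0586). They had 0.26 without DMSO 48 h replicate 3. Mitotic genes were positive in 35 of 37, with a median of 0.09 and 0 called (camera adjusted p = 0.00287; adjusted p = 0.546 with an estimated correlation), TOP2A among them (0.38 ± 0.14). They did not pass without GSI 48 h replicate 2 (0.00, adjusted p = 0.586) or DMSO 48 h replicate 3 (0.04, 0.226). They had 0.19 without GSI replicate 1, 0.19 without DMSO replicate 2 and 0.15 without GSI replicate 3.

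Growth and metabolic lists were lower at 48 h, with 0 members called by limma except in the noncoding list. Of 23 glycolytic genes, 22 were negative, with a median of -0.45, and -0.30 without DMSO 48 h replicate 1 (camera adjusted p = 1.25e-07; adjusted p = 0.318 with an estimated correlation), and the lactate dehydrogenase gene LDHA differed by -0.65 ± 0.19 (0.179, and 0.0356 with the pairing). Ribosome biogenesis genes were negative in 35 of 35, with a median of -0.32, and -0.21 without GSI 48 h replicate 1 and -0.18 without DMSO 48 h replicate 2 (camera adjusted p = 2.51e-09; adjusted p = 0.428 with an estimated correlation), and PUS7 differed by -0.92 (0.189, and 0.0314 with the pairing). Ribosomal proteins were negative in 50 of 50 (median -0.14, and -0.22 without DMSO 48 h replicate 1; camera adjusted p = 2.23e-05; adjusted p = 0.524 with an estimated correlation), RPS19 at -0.35 ± 0.15. Oxidative phosphorylation genes were negative in 30 of 30 (median -0.14, and -0.22 without GSI 48 h replicate 2; camera adjusted p = 0.000875; adjusted p = 0.524 with an estimated correlation), COX10 at -0.44 ± 0.13. Nucleotide synthesis genes were negative in 21 of 25 (median -0.23, and -0.11 without DMSO 48 h replicate 2; camera adjusted p = 0.000112; adjusted p = 0.428 with an estimated correlation), MTHFD1L at -1.15 (0.287, and 0.0150 with the pairing). Of the noncoding growth genes, CYTOR fell (-0.77 ± 0.11), as did 1 over the list alone, and the median was -0.18, and -0.08 without DMSO 48 h replicate 3 (camera adjusted p = 0.00287; adjusted p = 0.223 with an estimated correlation). Their SNHG4 differed by -0.66, with probes from -1.48 to -0.66. The ATF4 amino acid response was negative in 24 of 26 (median -0.51, camera adjusted p = 0.000328; adjusted p = 0.524 with an estimated correlation), TRIB3 at -0.72 ± 0.36. This list rested on single arrays: it did not pass without GSI 48 h replicate 1 (-0.28, adjusted p = 0.0860), and without DMSO 48 h replicate 3 its median was -0.06 and the test pointed up (0.918). It was -0.83 without DMSO replicate 1, -0.83 without DMSO replicate 2 and -0.86 without GSI replicate 3. Without DMSO 48 h replicate 3 ribosomal proteins did not pass (-0.06, adjusted p = 0.168), and oxidative phosphorylation did not without GSI 48 h replicate 1 (-0.09, 0.117) or DMSO 48 h replicate 2 (-0.06, 0.127).

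**Figure D2:**
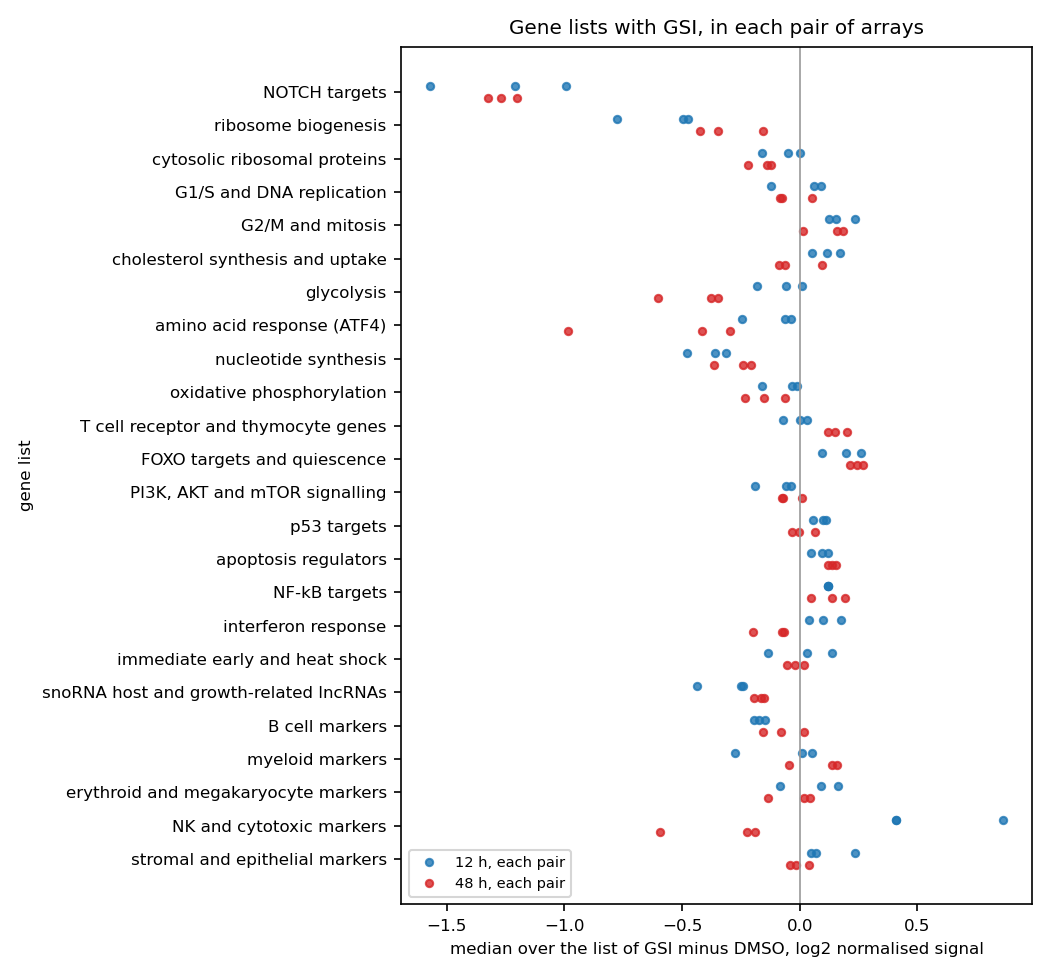
Median log2 difference, GSI minus DMSO, over each of the 24 gene lists at 12 h and 48 h, with 1 point for each pair of arrays. The points of NOTCH targets lie from -1.57 to -0.99 at 12 h and from -1.32 to -1.20 at 48 h.

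The other 12 lists did not pass at 48 h. Their medians were -0.02 for DNA replication (camera adjusted p = 0.917), -0.02 for cholesterol synthesis with the test pointing up (0.994), -0.04 for PI3K signalling (0.0926), -0.03 for p53 targets with the test pointing up (0.234) and -0.09 for immediate early genes with a positive mean (0.994). Apoptosis regulators (0.18, 0.0612) and interferon response genes (-0.13, 0.0868) did not pass but did with the pairing (0.0439 and 0.0409). Markers of other cells had medians of -0.05 for B cells with a positive mean (0.427), 0.01 for myeloid (0.519), -0.04 for erythroid (0.407), -0.39 for natural killer (0.0868) and -0.02 for stromal cells (0.994). Within these lists BTG2, the proapoptotic BIK (1.01 ± 0.20), EGR2 and the natural killer receptor gene NCR3 (1.15 ± 0.22) rose, while KLRD1 and the B cell coactivator gene POU2AF1 (-0.56 ± 0.11) fell. EGR1 differed by 2.03 ± 0.52 (adjusted p = 0.121) and passed with the pairing (0.0252).

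At 48 h limma called 324 features, 107 higher and 217 lower with GSI, of which 250 changed at least 2-fold, and 1121 with the arrays paired (489 and 632). Groups did not overlap for 14.9% of features, against 10% by chance for arrays that do not pair. The count was 198 without DMSO replicate 1, 199 without GSI replicate 1, 202 without DMSO replicate 2, 205 without GSI replicate 2, 197 without DMSO replicate 3 and 170 without GSI replicate 3. In the same order, 13, 17, 10, 12, 14 and 16 of 49 named calls were lost. BIK and POU2AF1 were lost in every case. AHNAK, DMBT1, HEY1, HES1, HES5, CCR9, GATA3, CCR7, CD83 and NCR3 were lost in most cases, and RASGRP1, SVOPL, PDE4B, NOTCH3 and SHQ1 in some.

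Long noncoding RNAs, the subject of the custom probes, took part in both responses. LINC01120 fell by 3.47 ± 0.39 at 12 h and by 3.65 ± 0.39 at 48 h. The transcript listed as TCONS_00003874 fell by 3.27 ± 0.39 at 12 h and was at least 11.4-fold lower at 48 h, when its probe was not well above background with GSI, and ENST00000415154 fell by 4.04 ± 0.29 at 48 h. TCONS_00005405 was at least 5.18-fold and TCONS_00006755 at least 4.42-fold higher at 12 h, since neither was well above background in DMSO. At 48 h they rose by 2.56 ± 0.41 and 2.80 ± 0.45, with DMSO well above background on 1 of 3 arrays; both calls were lost without GSI 48 h replicate 1 (limma adjusted p = 0.0545 and 0.0503) or replicate 3 (0.0597 and 0.0540), and the former also without DMSO 48 h replicate 2 (0.0515). The 12 h call of TCONS_00006755 was lost without any 1 of 5 arrays (0.0531 to 0.0930), GSI 12 h replicate 2 being the exception.

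Of 7569 noncoding features, 61 changed at 12 h (11 rose and 50 fell), or 0.806%, against 136 of 13714 coding features (54 and 82), or 0.992% (Fisher's exact test across features, two-sided p = 0.179, odds ratio 0.811). At 48 h, 77 noncoding features changed (24 and 53), or 1.02%, against 197 coding features (67 and 130), or 1.44% (exact p = 0.00916, odds ratio 0.705). Noncoding features were dimmer, with a median log2 signal of -2.32 against 1.66. Within 4 equal bins of signal the 48 h shares differed in the dimmest (0.750% against 2.08%, exact p = 6.03e-05) and not in the next 3 (0.168, 0.687 and 0.157). With the pairing, 281 noncoding features changed at 12 h (127 and 154) and 304 at 48 h (129 and 175). Features are not independent replicates, and the class of custom probes was taken from the array design.

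The responses at the 2 times overlapped. Among 412 features changed at either time, 38 rose at both and 107 fell at both, against 0.325 and 1.33 for independent lists, and 0 changed in opposite directions. The arrays of the 2 times are separate, so the comparisons share no controls. They do share the estimate of each gene's spread, which came from all 12 arrays. A gene with a low estimate is easier to call at both times, so the numbers for independent lists are no exact benchmark. Across all features, which are not independent replicates, the log2 differences correlated with r = 0.451 and rho = 0.343. Of features called at 12 h, 70 of the 77 that rose and 154 of the 156 that fell had the same sign at 48 h. With the pairing, 455 features were shared.

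**Figure D3:**
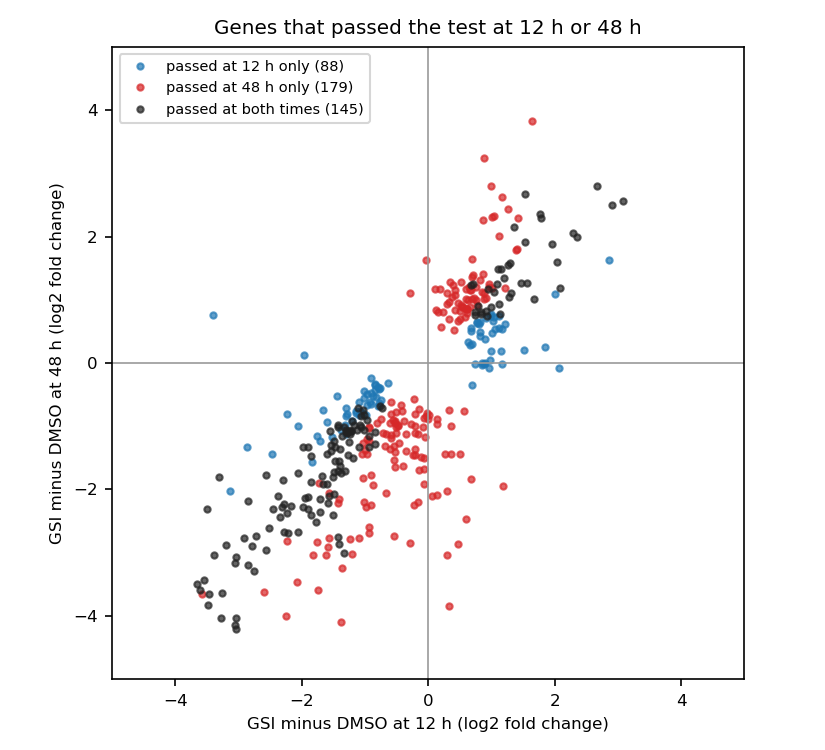
Log2 difference, GSI minus DMSO, at 12 h (horizontal) against 48 h (vertical) for each feature called at either time, coloured by whether it was called at both times or at 1. The 145 features called at both times all lie in the quadrants where both differences have the same sign.

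Whether an effect differed between the times was tested as the 48 h effect minus the 12 h effect. NOTCH targets showed no detectable difference, with a median of 0.04 (camera adjusted p = 0.913). No single feature passed: limma called 0 of 25384, with 885 at an unadjusted p under 0.05, fewer than the 1269 expected by chance. The serine protease gene HTRA1 came closest (-3.33, adjusted p = 0.134). With the pairing 4 were called, HTRA1, DMBT1, ENPP1 and 1 unnamed noncoding transcript, with slide as a block HTRA1, GBP2 and PTPN14, without DMSO 12 h replicate 3 NCCRP1 and 2 unnamed transcripts, and without GSI 12 h replicate 3 HTRA1. These few were named after their values were seen.

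As groups, 7 of 24 lists differed between the times by camera. Natural killer and cytotoxic genes had a median difference of -0.97 (adjusted p = 6.64e-06; adjusted p = 0.0390 with an estimated correlation, and 0.344 when that was combined with the pairing), with 4 of 10 lower over the list alone, and -0.56 without GSI 12 h replicate 1. Ribosome biogenesis genes were less reduced relative to DMSO at 48 h (0.23, camera adjusted p = 3.54e-05, and 0.908 with an estimated correlation). They did not pass without GSI 48 h replicate 2 (0.10, adjusted p = 0.0713). The median was 0.39 and 0.14 without DMSO 12 h replicates 1 and 2 and 0.43 and 0.13 without DMSO 48 h replicates 2 and 3. Ribosome biogenesis genes did not recover with GSI: from 12 h to 48 h their median change was -0.57 with GSI and -0.89 in DMSO. Glycolytic genes (-0.35, adjusted p = 0.000148) and interferon response genes (-0.23, 0.00356) were lower at 48 h relative to 12 h, and T cell receptor genes higher (0.15, 0.000148), with adjusted p = 0.908, 0.908 and 0.889 with an estimated correlation. Glycolytic genes did not pass without GSI 48 h replicate 2 (-0.17, adjusted p = 0.0528). They had -0.52 and -0.23 without DMSO 48 h replicates 2 and 3. T cell receptor genes had 0.05 without GSI 12 h replicate 1 and 0.05 without DMSO 12 h replicate 3. Interferon genes did not pass without GSI 12 h replicate 2 (adjusted p = 0.0634), DMSO 48 h replicate 2 (-0.07, 0.212) or DMSO 12 h replicate 3 (-0.10, 0.0836). They had -0.11 without GSI 12 h replicate 1 and -0.10 without GSI 48 h replicate 3. The ATF4 list (-0.41, adjusted p = 0.0453) and ribosomal proteins (-0.10, 0.0168), both with adjusted p = 0.908 with an estimated correlation, were the least firm. The first did not pass with slide as a block (0.103). The second turned positive when arrays were scaled to their median (0.04, 0.261), where the median of all genes was 0.15. ATF4 genes did not pass without DMSO 12 h replicate 1 (adjusted p = 0.259) or 2 (0.0514), GSI 12 h replicate 2 (0.0634) or 3 (0.227), or GSI 48 h replicate 1 (-0.12, 0.784) or 2 (-0.20, 0.204), and turned to 0.14 without DMSO 48 h replicate 3 (0.261). They had -0.72 and -0.69 without DMSO 48 h replicates 1 and 2 and -0.77 without GSI 48 h replicate 3. Ribosomal proteins did not pass without DMSO 12 h replicate 1 (-0.05, adjusted p = 0.281) or 2 (0.0617), GSI 48 h replicate 1 (-0.06, 0.426) or 2 (0.0528) or DMSO 48 h replicate 3 (-0.02, 0.885). They turned to 0.02 without GSI 12 h replicate 3 (0.980). They had -0.16 and -0.17 without GSI 12 h replicates 1 and 2, -0.17 without DMSO 12 h replicate 3, -0.16 without DMSO 48 h replicate 1 and -0.15 without GSI 48 h replicate 3.

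The solvent control was compared between the times to show what changed without GSI. By 48 h ADM, a peptide hormone gene induced by low oxygen, had risen by 6.39 ± 0.75, the mitophagy receptor gene BNIP3 by 4.58 ± 0.66, the glycolytic regulator gene PFKFB4 by 4.06 ± 0.62, BHLHE40 by 4.01 ± 0.94 and FGFBP2 by 3.68 ± 0.99. The metallothionein gene MT1G fell by 3.15 ± 0.57 and the potassium channel gene KCNJ2 by 2.79 ± 0.53. MT1M was at least 6.32-fold, CLCA1 at least 3.35-fold and GSTTP2 at least 3.10-fold lower, being not well above background at 48 h. Without DMSO 12 h replicate 1 the bound of CLCA1 was 1.76-fold, and that of GSTTP2 was under 2-fold without replicate 2 and 5.38-fold without replicate 3. Metallothionein genes are near-identical in sequence, so their probes may not tell them apart. Glycolytic genes rose in 9 of 23 cases (14 over the list alone), with a median of 0.68 (camera adjusted p = 3.91e-09; adjusted p = 0.839 with an estimated correlation), and PDK1 (2.68 ± 0.55) and SLC2A3 (1.98 ± 0.35), picked after their values were seen, were among them. Ribosome biogenesis genes fell in 24 of 35 cases (32 over the list alone), with a median of -0.89 (camera adjusted p = 4.07e-16; adjusted p = 0.839 with an estimated correlation). Nucleotide synthesis (-0.28, 5 fell and 6 over the list alone, 0.00855), ribosomal proteins (0.20, 0 called by limma, 6.42e-05), ATF4 genes (0.49, 1 rose and 1 fell, 0.00855) and FOXO targets (0.23, 2 rose, 0.0401) also passed, each with adjusted p = 0.839 with an estimated correlation. Ribosomal proteins had 0.11 without DMSO 48 h replicate 3.

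Of the lists that did not pass in DMSO, NOTCH targets had a median of -0.33 (camera adjusted p = 0.0722), and NRARP, FJX1 and SHQ1, named after their values were seen, fell. Medians were -0.24 for mitotic genes (0.0860), -0.14 for DNA replication (0.278), 0.11 for cholesterol synthesis (0.278), -0.03 for oxidative phosphorylation (0.485), -0.10 for T cell receptor genes (0.302), -0.13 for PI3K signalling with a positive mean (0.742) and 0.11 for p53 targets (0.278). They were -0.09 for apoptosis regulators with a positive mean (0.958), 0.04 for NF-kB targets (0.343), -0.13 for interferon (0.923), -0.04 for immediate early genes with a positive mean (0.958) and -0.30 for noncoding growth genes (0.420). Markers of other cells had -0.09 for B cells (0.593), -0.51 for myeloid (0.278), -0.05 for erythroid with a positive mean (0.958), 0.01 for natural killer (0.958) and 0.12 for stromal cells (0.302).

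In DMSO limma called 2409 features (978 rose and 1431 fell), 852 of them at least 2-fold, and the groups did not overlap for 30.2%, against 10% by chance. Time and slide were partly mixed, since slide 4 alone held both times. With slide as a block 211 features were called (137 rose and 74 fell), and 158 with scan date as a block (104 and 54). There were 102 with only the compared arrays in the fit (75 and 27), 978 with arrays scaled to their median (371 and 607), and 0 on slide 4 alone by limma. The excess of falls is therefore not firm. With slide as a block the medians were 0.35 for glycolysis (camera adjusted p = 4.32e-05), -0.85 for ribosome biogenesis and 0.05 for ribosomal proteins (0.0306), and ribosomal proteins went to -0.0016 with scan date as a block (0.381). ADM (5.59, adjusted p = 0.0374), PFKFB4 (3.35, 0.0440) and MT1G (-3.13, 0.0402) passed with the slide block and the other 7 named genes did not. The count was 1175 without DMSO 12 h replicate 1, 445 without its replicate 2, 406 without DMSO 48 h replicate 1 and 435 without its replicate 3. Without those 4 arrays 2, 4, 6 and 4 of the 10 named calls were lost, and 2 and 1 without DMSO 12 h replicate 3 and DMSO 48 h replicate 2; BHLHE40, FGFBP2, GSTTP2, KCNJ2, CLCA1 and MT1G were concerned. FOXO targets did not pass without DMSO 12 h replicate 2 (0.14, adjusted p = 0.0791) or 3 (0.0913) or DMSO 48 h replicate 3 (0.00, 0.188), nucleotide synthesis without DMSO 12 h replicate 3 (-0.16, 0.194), and ATF4 genes without DMSO 48 h replicate 3 (-0.05, 0.829). ATF4 genes had 0.78 without DMSO 48 h replicate 1. The DMSO 48 h arrays enter both this comparison and the 48 h GSI effect, so that noise in those arrays moves the 2 in opposite directions.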

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

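The tests of probes near background, of cells of another type, of single DMSO arrays and of the culture-time rise in this part were chosen only after the results were seen.

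Values of 7 lists stood out because the test of the difference itself (camera on the 48 h effect minus the 12 h effect) found a list whose response to GSI differed between the times. With an estimated correlation only natural killer and cytotoxic genes passed (adjusted p = 0.0390, and 0.344 when that was combined with the pairing), and the other 6 did not (adjusted p = 0.889 to 0.908 by camera). At the preset correlation ribosome biogenesis genes had a median difference of 0.23 (adjusted p = 3.54e-05; 0.10 to 0.43 with 1 array left out), and all 35 were negative at both times. Ribosomal proteins had -0.10 (adjusted p = 0.0168; -0.17 to 0.02). The ATF4 amino acid response had -0.41 (adjusted p = 0.0453; -0.77 to 0.14). T cell receptor and thymocyte genes had 0.15 (adjusted p = 0.000148; 0.05 to 0.19), and RAG1 among them had a difference of 1.66 ± 0.34 (unadjusted p = 0.000454, adjusted p = 0.612 by limma). Interferon response genes had -0.23 (adjusted p = 0.00356; -0.31 to -0.07), with OASL at -1.50 ± 0.32 and IFIT3 at -1.39 ± 0.42 (unadjusted p = 0.000587 and 0.00707, adjusted p = 0.612 and 1.0 by limma). RAG1, OASL and IFIT3 were picked after their values were seen. Glycolytic genes had -0.35 (adjusted p = 0.000148; -0.52 to -0.17) and natural killer and cytotoxic genes -0.97 (adjusted p = 6.64e-06; -1.04 to -0.56, the last without GSI 12 h replicate 1). As many as 7 lists or more were called in 50 of 100 drawn splits of the arrays within each time, with up to 14 in another split, and in 8 of the 18 others that part all 6 pairs of arrays, so chance is not excluded for the count of lists.

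Natural killer and cytotoxic genes had a median of 0.63 with GSI at 12 h, with 0 of 10 called by limma (camera adjusted p = 0.00226; adjusted p = 0.113 with an estimated correlation), and of -0.39 at 48 h (camera adjusted p = 0.0868). Dim probes may account for part of the size, since over the 7 members well above background on all 12 arrays the median difference was -0.36 against -0.97 for all 10. Of those 7, 3 differed between the times by over 2 standard errors. These were GZMA (-3.19 ± 0.56), NKG7 (-0.98 ± 0.35) and PRF1 (-0.96 ± 0.31), with unadjusted p = 0.000127, 0.0182 and 0.00994 by limma. The list was flagged for this same difference, and limma called 0 of 25384 features for it after adjustment. Whether dim probes account for all of it is therefore not settled by these 3 genes. A changed share of contaminating cells that moved the whole list together is argued against by 2 members, NCR3 (1.15 ± 0.22) and KLRB1 (1.39 ± 0.40). Their 48 h effects were opposite to the list's median by over 2 standard errors, though KLRB1 did not pass by limma (adjusted p = 0.188). Both also had positive effects at 12 h (0.66 and 1.32), and which cells express them was not measured. A changed share behind the other members is therefore not excluded. NKG7, an abundant gene of such cells, had a mean log2 signal of 3.88 in DMSO and 3.51 with GSI at 48 h. For every array the labels name CUTLL1, a single cell line, and no other cells, sort or gate. A changed share of natural killer cells behind the other members therefore has no named source, though these values do not exclude it. The other reading is a response of CUTLL1 cells to GSI that changes with time. For that response, GZMA, NKG7 and PRF1 are a hypothesis only.

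Glycolytic genes had a lower GSI effect at 48 h than at 12 h, which did not pass with an estimated correlation (camera adjusted p = 0.908). A single DMSO 48 h array is argued against as the cause, since the smallest median difference without any 1 of them was -0.23, although without GSI 48 h replicate 2 it was -0.17 and did not pass (adjusted p = 0.0528). The list rose between 12 h and 48 h with GSI (median 0.41) as well as in DMSO (0.68). Whether GSI slowed a culture-time rise, or lowered these genes at 48 h in another way, cannot be told apart from 2 times. The 0.41 lay between the bounds set for this question. Those bounds could not have decided it, since per gene the change with GSI is the DMSO change plus the difference of effects.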

How the results depend on the processing

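Normexp on median spot signals, the pairing within each time, scan date, slide 4 alone and the slide block for gene lists were chosen only after the data were seen; the other alternatives were set beforehand. Normexp on mean spot signals was not run. Counts of genes stayed within 1.5 times of 233 at 12 h and 324 at 48 h under quantile normalisation, median scaling, normexp, probes above background on all arrays, the mean of probes, the deposited table, an intensity trend with robust prior and array weights (172 to 307 and 236 to 373). Of the calls at 12 h and 48 h, 216 and 306 were shared with quantile normalisation, 145 and 210 with median scaling, 180 and 210 with normexp and 178 and 259 with the deposited table. Median scaling moved the median of all genes from 0.00337 to 0.106 at 48 h, from 0.0104 to 0.148 for the difference between times and from -0.0653 to -0.134 in DMSO over time. Of 2115 values of called named genes under all alternatives, 1623 kept the call and 492 lost it. Of 3767 values of named genes not called, 183 gained a call, 3584 did not, and 30 of these changed sign, while 0 called ones did. For lists 485 values kept the call, 144 lost it and 3 turned. Signal over background limits dim features, since 21437 of 25384 were well above it on all arrays and the others had a bound or a noisier value in some group. Where no cause is named, the cause was not tested.

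Without a filter on dim probes 50437 features were tested, and calls fell to 95 at 12 h (93 shared), 132 at 48 h (129 shared), 9 in DMSO over time, 29 and 24 noncoding and 60 for the overlap, while lists in DMSO rose to 10. With only the compared arrays in the fit, and so fewer residual degrees of freedom, 91, 196 and 102 genes were called at 12 h, 48 h and in DMSO. On slide 4 alone, with 1 to 2 arrays per group, 0 genes were called in each of these 3, with 3 lists at 12 h, 4 for the difference between times and 12 in DMSO. In DMSO over time, of 2409 genes, median scaling called 978 and normexp 4425. At 48 h normexp called 46 noncoding features.

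With replicate number as a block across times, 404, 521 and 4738 genes were called at 12 h, 48 h and in DMSO, with 108 and 138 noncoding features. With the replicate block within each time, which pairs GSI with DMSO, 1171 and 1121 genes (228 and 317 of the calls shared), 281 and 304 noncoding features, an overlap of 455 and 4 genes for the difference between times were called. Of named calls the pairing lost CEBPE at 12 h and HEY1 at 48 h, and kept 43 of 44 and 48 of 49; it gained 33 of 93 and 26 of 87 others, and for lists cholesterol synthesis at 12 h and apoptosis and interferon at 48 h. The pair block changed no other call of a list at the preset correlation. Combined with an estimated correlation, it left 0 lists at 12 h, 48 h and for the difference, where NOTCH targets had adjusted p = 0.269 and 0.0999 at 12 h and 48 h, and 2 lists for the difference with fry. With slide as a block 463, 587 and 211 genes were called at 12 h, 48 h and in DMSO, 3 for the difference between times, and 12 lists in DMSO. The slide block kept 40 of 44 and 48 of 49 named calls at 12 h and 48 h, and gained 14 of 93 and 12 of 87 others. With scan date 358 and 158 genes were called at 12 h and in DMSO, and 2 for the difference.

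With an estimated correlation, 1 list was called at 12 h, 1 at 48 h, 1 for the difference between times and 0 in DMSO. With fry, which does not compare a list with other genes, the numbers were 3, 1, 1 and 3. List calls that other scalings, filters and blocks ended were mitotic genes at 12 h with normexp (adjusted p = 0.105), natural killer genes at 12 h without a filter (0.0520), ribosomal proteins for the difference with quantile normalisation (0.139), normexp (0.302), median scaling (0.261) and no filter (0.314), and ATF4 genes for the difference with normexp (0.0880), no filter (0.314), slide (0.103) and scan date (0.149). In DMSO they were ribosomal proteins with quantile normalisation (0.216), normexp (0.382) and scan date (0.381), ATF4 genes with normexp (0.120) and scan date (0.0580), nucleotide synthesis with quantile normalisation (0.0826) and FOXO targets with normexp (0.257) and the replicate block (0.0724). On slide 4 alone, with few arrays, the calls of mitotic (0.0518), FOXO (0.0734), noncoding growth (0.0698) and natural killer genes (0.0789) at 12 h, NF-kB targets at 48 h (0.205), and ribosome biogenesis (0.168), ATF4 (0.288) and T cell receptor genes (0.0961) for the difference ended.

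With single arrays left out, genes called ranged from 120 to 209 at 12 h, 170 to 205 at 48 h, 406 to 2618 in DMSO and 0 to 3 for the difference between times. Lists ranged from 7 to 13 at 12 h, 10 to 15 at 48 h, 5 to 9 for the difference and 4 to 8 in DMSO, with 13 at 12 h without GSI replicate 3. Among lists called in the main fit, the medians that turned were those of ribosomal proteins for the difference (-0.171 to 0.0222) and of ATF4 genes for the difference (-0.766 to 0.144) and in DMSO (-0.0473 to 0.779). For ATF4 genes at 48 h the test turned and the median did not (-0.857 to -0.0572). The medians of some called lists kept their sign but shrank to under 0.5 of the main value without 1 array. These were mitotic genes at 12 h (0.0414 to 0.256) and 48 h (0.00243 to 0.195), ribosomal proteins (-0.217 to -0.0624), oxidative phosphorylation (-0.222 to -0.0626), nucleotide synthesis (-0.348 to -0.115) and noncoding growth genes (-0.271 to -0.0756) at 48 h, as well as the ATF4 genes at 48 h. For the difference they were ribosome biogenesis (0.104 to 0.432), glycolysis (-0.525 to -0.171), T cell receptor (0.0468 to 0.192) and interferon genes (-0.313 to -0.0691), and in DMSO FOXO targets (0.000644 to 0.317). Medians of lists not called turned as well, such as glycolysis at 12 h (-0.192 to 0.0207).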

Other observations

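The lists of hypoxia-induced and metal-responsive genes were chosen only after ADM, BNIP3, PFKFB4 and BHLHE40, or MT1M and MT1G, had been seen to change, and those 6 genes were left out of them; the other tests in this part were set before their results were seen.

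Genes known to be induced by low oxygen were higher in DMSO at 48 h than at 12 h. Of 25 measured genes of that kind outside glycolysis (32 listed), 12 rose and 1 fell, with a median of 0.995 (camera p = 9.64e-11, adjusted p = 7.71e-10; adjusted p = 0.342 with an estimated correlation). AK4 rose by 3.47 ± 0.58, the collagen hydroxylase genes P4HA2 by 2.86 ± 0.65 and P4HA1 by 1.95 ± 0.41, the mitophagy receptor gene BNIP3L by 2.63 ± 0.46, ANKRD37 by 2.28 ± 0.51 and RORA by 1.91 ± 0.38, while KCTD11 fell by 1.19 ± 0.31. VEGFA differed by 1.66 ± 0.49 and did not pass (limma adjusted p = 0.0568). With slide as a block the median was 0.751 (camera adjusted p = 2.07e-08, and 0.431 with an estimated correlation) and 1 gene rose. That block cannot tell slide from time, because only slide 4 held DMSO at both times, with replicate 3 alone at 12 h. With GSI at 48 h the same list was lower than in DMSO, with 23 of 25 negative, a median of -0.389 and 0 called by limma (camera p = 1.82e-05, adjusted p = 4.86e-05; adjusted p = 0.342 with an estimated correlation), and at 12 h it was not (camera adjusted p = 0.832). The 48 h effect minus the 12 h effect had a median of -0.498, with 24 of 25 negative (camera adjusted p = 3.09e-05; adjusted p = 0.342 with an estimated correlation). The DMSO 48 h arrays enter the rise over time, the 48 h GSI effect and the difference of effects. Noise in those arrays can therefore raise the first and lower the others together, so they are not separate lines of support. No values with 1 array left out are given for this list. A candidate explanation is less oxygen in DMSO cultures after 48 h, and less of that with GSI if those cultures grew less. Neither oxygen nor cell number is in the data used here.

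Metal-responsive genes moved the other way in DMSO: 9 of 9 were lower at 48 h, with a median of -0.886 (camera p = 0.000165, adjusted p = 0.000331; adjusted p = 0.342 with an estimated correlation), and MT1A fell (-0.60 ± 0.15, limma adjusted p = 0.0338). With slide as a block 3 fell and the median was -0.988 (camera adjusted p = 4.52e-07, and 0.0962 with an estimated correlation). Slide cannot be told apart from time for this list either. With the correlation estimated, neither added list passed in any comparison, with or without slide as a block. For the metal-responsive list the medians of GSI minus DMSO were 0.0334 at 12 h and -0.207 at 48 h, and limma called 0 of the 9 at either time. Of the 9, 8 are metallothionein genes, whose probes may read near-identical genes, so those 8 are not separate witnesses.

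In DMSO over time, glycolytic genes were higher and ribosome biogenesis genes lower by camera at its preset correlation, and neither passed with an estimated correlation (adjusted p = 0.839 for both). Scaling is argued against as the cause, since at the smallest the medians of 0.676 and -0.892 went to 0.508 and -0.756 under another scaling. Slide cannot be told apart from time for either list. With slide as a block the medians were 0.352 and -0.850, and on slide 4 alone 0.456 and -0.802, but slide 4 is the only slide with DMSO at both times and holds 1 DMSO array of 12 h. The set bounds, at least 0.5 of the median and the same sign on slide 4, were met. They rest on that array and, through the slide block, on GSI 12 h replicate 3, whose deviations correlated with it (r = 0.543).

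The splits of the arrays of each comparison number 10, the real one included, too few for a share under 0.05. Genes called numbered 233 at 12 h, 324 at 48 h and 2409 in DMSO over time, against at most 2, 1 and 0 in the other splits, and noncoding features 61 and 77 against at most 0 and 1. In each of these 5 counts only 1 split, the real one, gave as many. The other splits mix the compared arrays within groups, which adds any real difference to the spread and lowers their calls. The size of the gap to the real split is therefore no measure of support. The 3 splits per comparison that part as many pairs of arrays as the real one called 0 genes, and the 6 others, which keep pairs together, called 0 to 2, 0 to 1 and 0. In DMSO over time these are same-numbered arrays of the 2 times, which were not taken as paired. For gene lists the real values were 7 at 12 h, 12 at 48 h and 6 in DMSO, against up to 10, 11 and 10, with as many in 6, 1 and 6 of 10 splits. Chance is not excluded for any of these list counts. Over both times 100 of 200 possible splits were drawn. The overlap of 145 genes was reached by 1 split, the real one, against at most 0 in others. This decides nothing, because mixing GSI and DMSO arrays within groups left at most 2 genes called at 12 h and 18 at 48 h in the other splits, too few for such an overlap. The set bound of a share under 0.05 was therefore the wrong one. For genes whose effect differed between the times the real value was 0 and the highest other gave 5. All 100 gave as many, which was fixed in advance because no count lies below 0, so this test decides nothing.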
